A study of Homo sapiens with 4 samples.

How the data were processed

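Gene expression was measured in 4 libraries of MDA-MB-231 cells, 2 in the EGFP positive and 2 in the EGFP negative group. RNA was selected by its polyA tail and made into stranded libraries, per the labels' protocols. Each library had a deposited table of raw fragment counts for 61471 gene names, per the file headers made by featureCounts 2.0.1 over exons grouped by gene name, with the GENCODE 46 basic annotation. Per the file headers the counting was of paired reads and used no strand option, so reads of a gene and of an overlapping or antisense gene could not be told apart. The aligner was not given in the sources used here. Subread and the builds GRCh37 and hg19 are named in the submitters' processing notes. The coordinates in the tables were those of GRCh38: 18610 of 18717 protein-coding genes (99.4%) lay within 5000 bp of their place in GENCODE 29 on that build. That match concerns the annotation used for counting and does not show to which build the reads were aligned. All coordinates given are GRCh38. Reads that fit a gene and its processed copy equally could be placed on either, and pseudogenes held 6.92 to 7.68% of the counts. The copy EEF1A1P5, for example, had 49315 counts in EGFP positive library 1 and EEF1A1 43670.

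Group and replicate number were taken from the labels. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16413. TMM factors were 0.987 to 1.009. The main test was edgeR 4.0.16 (R 4.3.3), a quasi-likelihood fit of all 4 libraries with group as the only term, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 7.52%. A permutation of 2 against 2 libraries cannot reach p = 0.05: the smallest exact two-sided p is 0.33. CPM values were computed here from the deposited counts with TMM-scaled library sizes. The standard error of a log2 fold change was the fold change over the square root of the test's F statistic. Replicate libraries were compared first: chi-square per degree of freedom was 2.14 in EGFP positive and 6.71 in EGFP negative libraries, above sampling noise, so no library was counted as a duplicate. Pearson's r of log2 CPM, across genes, was 0.9949 and 0.9917 within groups and 0.9779 to 0.9799 between groups.

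Gene lists, 36 in all, were fixed before the data were examined, as were the design, the rule for named genes and all alternatives except a correction for GC content and length. Lists and chromosomes were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and at least 3 measured genes, adjusted over 36 lists or over the 23 chromosomes 1 to 22 and X. Of 36 lists 13 passed, 8 higher and 5 lower, and the H2B list among the lower ones served only as a check of the labels. The result of 1 of the 13 and the values of some genes are not reported here. None passed with an estimated correlation. With fry 11 lists passed, 7 of the 13 and 4 that camera had not called, while 6 of the 13 lost their call. Fry asks whether the genes of a list move on balance in one direction without comparing them with other genes. Bins of 20 Mb were tested by camera with the preset correlation only.

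Named genes followed a rule. From protein-coding genes that passed, had at least 5 CPM in the higher group and did not overlap between groups, the 12 with the largest change in each direction were taken. From each list came up to 4 members that passed with the smallest adjusted p, or, where none passed, up to 2 with the highest level. Every measured H2B gene was added as a check of the labels. ITGA6, TNS1, COL4A1, CORO1A, CCN1, CCN2, NT5E, ADAMTS1, FGF5, EEF1A1 and the pseudogenes lie outside that rule. They were chosen after their values were seen, as were further genes named in the closing section.

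The scripts were tested on simulated counts drawn from the means and library sizes of 16413 genes, with 200 genes changed. For the comparison of EGFP negative with EGFP positive, edgeR recovered 56.7% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 1 false call among 159, of which 4 were genes of the shifted list described next. A list of 25 genes shifted 1.3-fold had a camera adjusted p = 3.2e-21 with the preset correlation and 0.26 with an estimated one, and 0 of 30 unchanged lists were called by either. In this simulation, with 2 residual degrees of freedom, the estimated correlation thus missed a shift of that size. Its genes were drawn independently in a single run, so it cannot say which correlation suits the measured lists. Estimates there ran from -0.118 (metastasis to bone) to 0.694 (mitochondrially encoded genes).

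Alternatives were RLE size factors, upper quartile scaling, no filter and a stricter filter on low counts (1 CPM in at least 2 libraries and a summed count of 100), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn with the tested genes kept, and the GC and length correction. Figures were drawn with matplotlib 3.10.9.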

Results

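RNA of MDA-MB-231 cells, a human line of triple-negative breast cancer, was sequenced in 4 libraries. The cells carried a fusion of histone H2B with the green fluorescent protein EGFP and a red fluorescent protein driven by a viral promoter. Labels put 2 libraries in the EGFP positive group, described as cells without increased extravasation, and 2 in the EGFP negative group, described as cells with increased extravasation. Extravasation is the passage of tumour cells out of a blood vessel. The series title names polyploidy and adhesion to the matrix, and the labels used here do not state the ploidy of either group. Gene counts summed to 11620005 and 11445076 in EGFP positive libraries 1 and 2, and to 12635576 and 11620076 in EGFP negative libraries 1 and 2. A count of 3 corresponded to 0.237 to 0.262 CPM (counts scaled to a common library total) in each library. Counting intervals and floors cover counting error only.

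The single comparison asked which genes differed between EGFP negative cells, labelled with increased extravasation, and EGFP positive cells, labelled without it. EGFP status and extravasation status changed together, so no difference can be assigned to either, or set apart from other differences between the populations. Fold changes are EGFP negative over EGFP positive, levels are means in CPM over n = 2 libraries, adjusted p-values of genes come from edgeR's quasi-likelihood test and those of gene lists from camera, both with Benjamini-Hochberg adjustment and two-sided. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Standard errors of the log2 fold changes of the 150 named genes that passed ran from 0.066 to 0.564, with a median of 0.102; those of the genes that matter most are given beside them.

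Histone H2B transcripts separated the groups as a check of the labels. H2BC11 (GRCh38 chromosome 6, 27125897 to 27132795) was at 654 ± 21.8 CPM (SD, n = 2) in EGFP positive cells and at 6.28 ± 1.12 CPM (SD, n = 2) in EGFP negative cells, a log2 fold change of -6.70 ± 0.12 (SE; adjusted p = 1.4e-13). Its counts were 7733 and 7352 in the EGFP positive libraries and 88 and 64 in the EGFP negative ones, so that the EGFP negative level was 0.96% of the EGFP positive level. H2BC11 took 90.2% of the counts of the H2B list in EGFP positive cells and 9.55% in EGFP negative cells. The libraries were selected by polyA tail, so these are not shares of all H2B transcripts in the cells. The labels do not say which H2B gene the fusion was built from, and counts per gene cannot separate transcripts of the fusion from those of the chromosomal gene. H2BC15, H2BC6 and H2BC17 were also lower in EGFP negative cells, with log2 fold changes of -1.74, -1.84 and -1.95 at 4.03 to 4.72 CPM in EGFP positive cells. These near-identical genes share sequence with H2BC11, so their values are uncertain. The other 5 measured H2B genes did not pass, with H2BC12 at 36 and 36.8 CPM, H2BC5 at 11.4 and 8.22 CPM, and log2 fold changes of -0.32 for H2BC12L, 0.41 for H2BC18 and 0.39 for H2BC21. As a list, H2B genes were lower, with 0 higher and 4 lower of 9 (0 and 5 adjusted over the list alone). Camera gave an adjusted p = 1.0e-12, and an adjusted p = 0.27 with an estimated correlation. The list mean was -1.35 and its median -0.48, with H2BC11 far below the rest. Since the groups are named for EGFP, which the cells carried as a fusion with H2B, this call belongs to the check of the labels and is not a separate finding.

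Beyond H2B, genes changed in both directions. EGFP negative cells had higher levels of ALDH3A1, an aldehyde dehydrogenase (adjusted p = 5.5e-08), the cancer-testis gene SPANXB1 (1.78 and 88.5 CPM), the lymphocyte receptor gene CD96 (0.52 and 18.9 CPM), the kinase gene RPS6KA2 (3.34 and 36.5 CPM) and the collagen VI gene COL6A2 (2.04 and 22.1 CPM, log2 fold change 3.44 ± 0.23, SE). They had lower levels of CYP24A1, which inactivates vitamin D (24.8 and 1.07 CPM, log2 fold change -4.51 ± 0.22, SE, adjusted p = 6.5e-09), the kinase gene MUSK (30.4 and 1.79 CPM), THBS2 (37 and 2.9 CPM), the phosphodiesterase gene PDE1C (128 and 12.1 CPM), the metastasis suppressor KISS1 (44.9 and 4.22 CPM) and the Wnt ligand WNT5A (5.85 and 0.707 CPM). ALDH3A1 had 3 and 1 counts in the EGFP positive libraries, at or under the floor of 3, and 339 in the EGFP negative ones together, a ratio of 81.1 with a 95% counting interval of 31.4 to 299. FRMPD4 had 150 counts in the EGFP positive libraries and 2 in the EGFP negative ones, a ratio of 78.4 with a 95% counting interval of 21.3 to 653. Also among the 12 largest changes upward were GPRC5C, SLCO3A1, ARHGAP30, SCNN1A, MYO1F, CFP and KRT83, with log2 fold changes of 3.25 to 3.95, and among the 12 downward NRK, SEMA3E, ACOXL and FAT3, with -3.53 to -2.79. KRT83 and SPANXB1 belong to families of near-identical copies, so their values are uncertain.

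In all, 1543 genes were higher and 1552 lower in EGFP negative cells among 16413 tested, 18.9% of the genes. At least a 2-fold change was shown by 372 of the higher and 325 of the lower genes. Both libraries of one group lay above both of the other for each of the 3095 called genes, and for 57.4% of tested genes against 33.3% by chance. The counts depended on single libraries. They were 784 higher and 715 lower without EGFP positive library 1, 720 and 732 without EGFP positive library 2, 2157 and 2339 without EGFP negative library 1, and 2477 and 2465 without EGFP negative library 2. DESeq2 called 1044 higher and 997 lower.

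**Figure D1:**
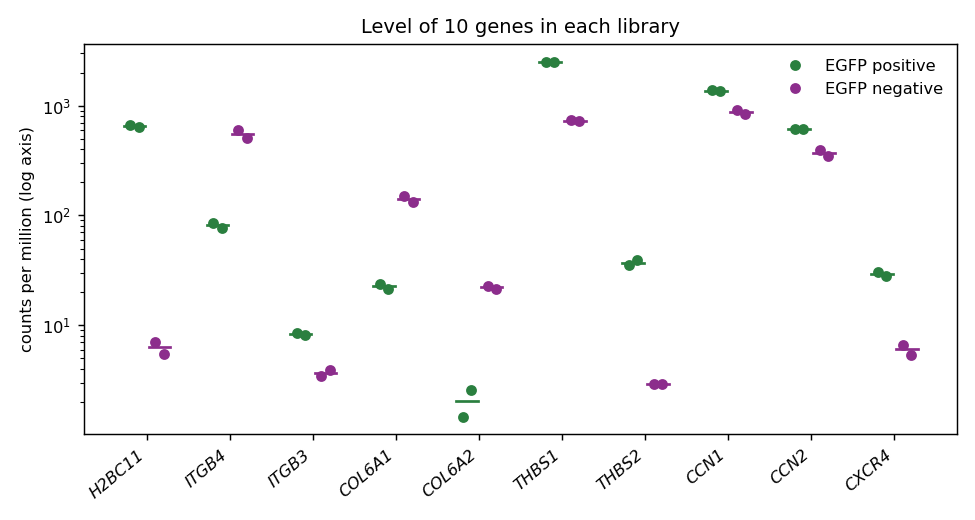
Level of 10 genes in CPM on a log axis, with a point for each library and a line at the mean of each group (n = 2). H2BC11, ITGB3, THBS1, THBS2, CCN1, CCN2 and CXCR4 lie lower in both EGFP negative libraries, and ITGB4, COL6A1 and COL6A2 higher.

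Integrins, the receptors that bind cells to matrix, were mostly higher in EGFP negative cells. The largest change was in ITGB4, the beta subunit of the laminin receptor of hemidesmosomes (chromosome 17, 75721328 to 75757818), which rose from 81.5 ± 6.61 to 550 ± 66 CPM (SD, n = 2), 6.75-fold (adjusted p = 6.1e-10). Its partner ITGA6 was at 593 and 623 CPM and did not pass (adjusted p = 0.57). The collagen receptor subunits ITGA2 (376 and 689 CPM, log2 fold change 0.88 ± 0.08, SE) and ITGA10 (3.81 and 11.9 CPM) rose, and ITGB3 fell from 8.32 to 3.7 CPM (adjusted p = 0.0023). Of 12 measured integrins, 7 were higher and 1 lower (8 and 1 adjusted over the list alone). The list passed (adjusted p = 2.3e-07, and adjusted p = 0.27 with an estimated correlation).

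Components of focal adhesions, which couple integrins to actin, changed in both directions, with 12 higher and 7 lower of 34 (14 and 7 adjusted over the list alone). The tensin genes differed among themselves: TNS1 rose from 14.1 to 25.8 CPM, TNS2 from 35.5 to 88.2 CPM and TNS4 from 0.607 to 5.3 CPM, while TNS3 fell from 182 to 114 CPM. The scaffold gene NEDD9 fell from 19.9 to 3.13 CPM (log2 fold change -2.66 ± 0.21, SE, adjusted p = 8.8e-07). The list did not pass (adjusted p = 0.087; 0.0064 without EGFP negative library 2).

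Several genes of the basement membrane were higher in EGFP negative cells and several abundant transcripts of the interstitial matrix lower. In the basement membrane list 7 were higher and 1 lower of 17 (9 and 2 adjusted over the list alone; adjusted p = 3.7e-05), among them COL7A1 (65.3 and 156 CPM), COL18A1 (45.4 and 101 CPM), LAMA5 (298 and 656 CPM) and LAMB1 (141 and 240 CPM). The lower member was COL4A1 (120 and 85.7 CPM), and 9 of the 17 were not called. With an estimated correlation the basement membrane list gave an adjusted p = 0.45, and 0.072 by fry. The interstitial matrix list had 6 higher and 9 lower of 20 (6 and 9 adjusted over the list alone; adjusted p = 8.7e-04 in the lower direction, and adjusted p = 0.4 with an estimated correlation). THBS1, encoding thrombospondin 1, fell from 2500 ± 17.4 to 730 ± 10.3 CPM (SD, n = 2), 3.42-fold lower, and THBS2 and COL8A1 (338 and 99.4 CPM) also fell. Collagen VI moved the other way: COL6A1 (chromosome 21, 45981770 to 46005048) rose from 22.6 to 142 CPM, 6.26-fold, COL6A2 is given above, and COL6A3 rose from 28.1 to 67.7 CPM. The interstitial list lost its call with no filter on low counts (adjusted p = 0.1) and by limma-voom (0.054).

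Matrix-remodelling genes split, with 15 higher and 9 lower of 36 (18 and 10 adjusted over the list alone). The cathepsin gene CTSD rose from 374 to 1100 CPM and the metalloproteinase gene ADAM8 from 135 to 307 CPM, while the collagenase gene MMP1 fell from 61.2 to 13.8 CPM. The list did not pass (adjusted p = 0.072), but passed without EGFP negative library 1 (0.03) or library 2 (0.0034).

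Surface molecules of migration and extravasation had 11 higher and 7 lower of 28 (13 and 7 adjusted over the list alone). CD82, a tetraspanin, rose from 46.8 to 110 CPM and BCAM, a laminin receptor, from 25.6 to 56.9 CPM. The chemokine receptor gene CXCR4 fell from 29.5 to 6.03 CPM and the adhesion molecule gene MCAM from 284 to 140 CPM. The list did not pass (adjusted p = 0.22; 0.029 without EGFP negative library 2). Cell-cell junction genes had 5 higher and 7 lower of 26 (7 and 8 adjusted over the list alone), with falls in the cadherin genes CDH4 (170 to 82.4 CPM) and CDH11 (39.8 to 18.5 CPM) and the desmosomal DSP (212 to 114 CPM). That list did not pass (adjusted p = 0.49; 0.038 by fry); its median log2 fold change was 0.18, its mean -0.08 and its tested direction lower.

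Lists of epithelial and mesenchymal state did not pass. Of the epithelial list 15 of 23 members passed the count filter, and CDH1 had 1 to 3 counts per library. The list had 3 higher and 2 lower of 15 (5 and 4 adjusted over the list alone, camera adjusted p = 0.74), with KRT19 rising from 260 to 391 CPM and EPCAM falling from 13 to 6.84 CPM. In the mesenchymal list 6 were higher and 2 lower of 18 (6 and 4 adjusted over the list alone; adjusted p = 0.19). S100A4 rose from 92.6 to 258 CPM and VIM, encoding vimentin, from 4200 to 5810 CPM, while TPM1 fell from 116 to 65.1 CPM. The median of that list was -0.01, its mean -0.02 and its tested direction higher. It passed by fry (adjusted p = 0.045) and without EGFP negative library 1 (0.03) or library 2 (0.029).

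Targets of YAP and TEAD, the effectors of Hippo signalling, were lower in EGFP negative cells, with 2 higher and 15 lower of 24 (2 and 16 adjusted over the list alone). Tissue factor, F3, fell from 598 to 185 CPM (log2 fold change -1.69 ± 0.08, SE, adjusted p = 3.8e-09), ANKRD1 from 785 to 280 CPM, TGFB2 from 95.5 to 37.7 CPM and CRIM1 from 832 to 432 CPM. CCN1 and CCN2, both widely used readouts of YAP, fell from 1370 to 873 and from 613 to 373 CPM. NT5E went against the list, from 375 to 757 CPM. The list passed (adjusted p = 6.4e-13, and adjusted p = 0.25 with an estimated correlation).

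TGF-beta targets had 9 higher and 2 lower of 21 (9 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.062; 0.0051 without EGFP negative library 2).

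Genes linked to metastasis of sublines of MDA-MB-231 to bone were lower throughout: 0 of the 8 measured were higher and 8 lower (0 and 8 adjusted over the list alone; adjusted p = 1.4e-28, and adjusted p = 0.25 with an estimated correlation). They were CXCR4, FST (219 and 46.7 CPM, log2 fold change -2.23 ± 0.10, SE, adjusted p = 2.2e-09), MMP1, SRGN (278 and 143 CPM), ADAMTS1 (93.2 and 44.9 CPM), CCN2, FGF5 (58.1 and 33.3 CPM) and IL11 (129 and 86.8 CPM). The list of metastasis to lung had 6 higher and 3 lower of 15 (7 and 4 adjusted over the list alone), with KRT81 rising from 37.3 to 305 CPM and LTBP1 from 37.4 to 83.8 CPM while MMP1 and NEDD9 fell. It did not pass (adjusted p = 0.087), but did without EGFP negative library 1 (0.024) or library 2 (0.0034). KRT81, like KRT83, belongs to a family of near-identical copies, so its value is uncertain. How far its reads were shared was not measured.

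**Figure D2:**
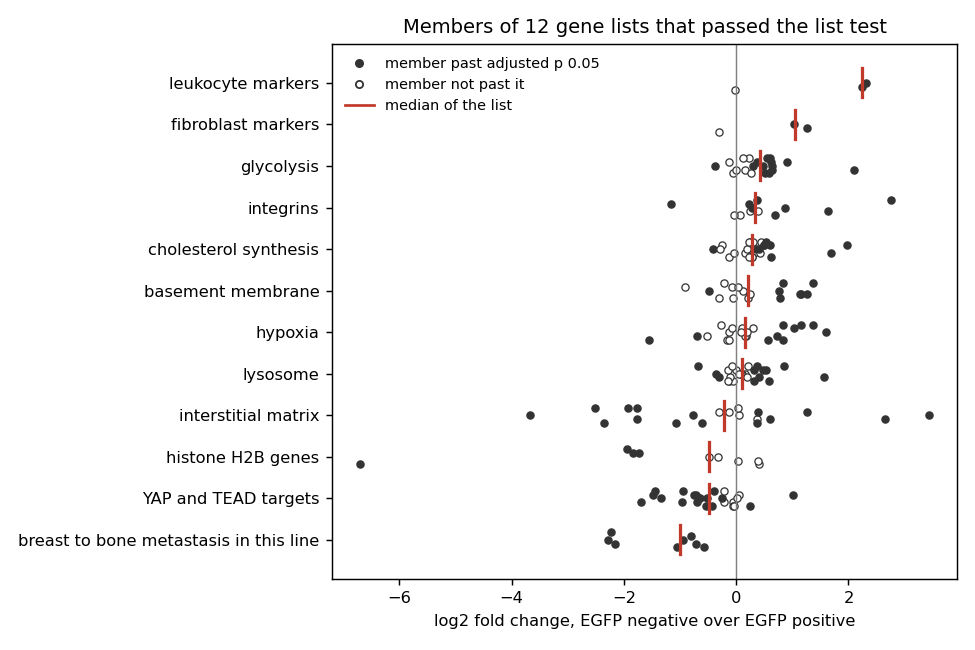
Log2 fold change, EGFP negative over EGFP positive, of each measured member of 12 gene lists that passed camera with a preset correlation. Filled points passed adjusted p 0.05, open points did not, and red lines mark list medians; heights within a list only spread the points. The 8 measured members of the bone metastasis list all lie below 0, and H2BC11 stands at -6.70.

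Glycolysis was higher in EGFP negative cells, with 12 higher and 1 lower of 20 (14 and 1 adjusted over the list alone; adjusted p = 3.8e-07, and adjusted p = 0.45 with an estimated correlation and 0.058 by fry). PKM rose from 2390 to 3720 CPM, ENO1 from 2090 to 3270 CPM, GAPDH from 1730 to 2540 CPM and ENO2 from 73.4 to 138 CPM. GAPDH has processed copies that took reads (4172 to 7231 counts per library on GAPDHP1), so its level is uncertain. Hypoxia-regulated genes had 8 higher and 2 lower of 23 (8 and 3 adjusted over the list alone; adjusted p = 0.0097, and adjusted p = 0.45 with an estimated correlation). DDIT4 rose from 83.1 to 251 CPM and NDRG1 from 53.8 to 119 CPM, while ADM fell from 83.5 to 28.3 CPM.

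Cholesterol synthesis and uptake genes had 9 higher and 1 lower of 25 (11 and 1 adjusted over the list alone; adjusted p = 3.7e-05, and adjusted p = 0.42 with an estimated correlation and 0.05 by fry, which no longer passed). INSIG1 rose from 21.7 to 69.6 CPM and FDFT1 from 37.4 to 57.3 CPM. Lysosomal genes had 9 higher and 3 lower of 25 (9 and 3 adjusted over the list alone; adjusted p = 0.011), led by CTSD and TPP1 (35.1 and 63.4 CPM). The lysosome list gave an adjusted p = 0.47 with an estimated correlation, 0.057 by fry and 0.056 without EGFP positive library 2.

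Proliferation and division genes moved little as lists. Cytokinesis and centrosome genes had 4 higher and 3 lower of 29 (5 and 3 adjusted over the list alone; adjusted p = 0.91), including NEDD1 (79.7 and 46.5 CPM) and LATS2 (80.4 and 49.7 CPM). G1/S genes had 6 higher and 3 lower of 30 (7 and 3 adjusted over the list alone; adjusted p = 0.24), with MCM6 at 95.7 and 142 CPM. G2/M genes had 4 higher and 2 lower of 31 (5 and 2 adjusted over the list alone; adjusted p = 0.37), and p53 targets 6 higher and 2 lower of 26 (6 and 3 adjusted over the list alone; adjusted p = 0.25). Their lists passed in none of the fits that left out 1 library.

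None of the following lists passed. Among all lists that did not pass, 4 passed by fry, 9 by limma-voom and 8 with no filter on low counts. Interferon response genes had 10 higher and 5 lower of 34 (14 and 5 adjusted over the list alone; adjusted p = 0.13). IFI44 rose from 7.63 to 18.8 CPM and OAS2 from 15.2 to 29.8 CPM, while BST2 fell from 86.1 to 23 CPM. Inflammatory cytokines had 2 higher and 5 lower of 24 (2 and 6 adjusted over the list alone; adjusted p = 0.095; 0.04 by fry), and immediate early genes 5 and 5 of 25 (7 and 8 adjusted over the list alone; adjusted p = 0.74). ATF4 and amino acid stress genes had 3 and 3 of 26 (3 and 5 adjusted over the list alone; adjusted p = 0.85). ER chaperones had 5 higher and 0 lower of 22 (5 and 0 adjusted over the list alone; adjusted p = 0.067; 0.038 by fry and 0.03 without EGFP negative library 1), and heat shock genes 0 and 5 of 17 (0 and 5 adjusted over the list alone; adjusted p = 0.1; 0.029 without EGFP negative library 2). Cytosolic ribosomal proteins had 2 higher and 1 lower of 45 (2 and 1 adjusted over the list alone; adjusted p = 0.27), and passed without EGFP positive library 1 (0.023) or EGFP negative library 2 (8.2e-06). Nuclear oxidative phosphorylation genes had 7 and 0 of 37 (7 and 0 adjusted over the list alone; adjusted p = 0.087), and mitochondrially encoded genes 1 and 3 of 13 (1 and 3 adjusted over the list alone; adjusted p = 0.14). Without EGFP positive library 1 both gave an adjusted p = 0.046, and without EGFP negative library 2 they gave 0.0038 and 0.033.

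Markers of other cell types were measured beside the matrix and adhesion genes. Of the leukocyte markers only 3 of 17 passed the count filter. LAPTM5 rose from 29.4 to 146 CPM and CSF1R from 1.34 to 6.42 CPM (2 higher and 0 lower; the counts were the same adjusted over the list alone; adjusted p = 3.9e-08, and adjusted p = 0.34 with an estimated correlation). CORO1A was at 3.21 and 3.17 CPM. Of the fibroblast markers only 3 of 14 passed the count filter, and 2 were higher and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.45 with an estimated correlation), namely COL6A3, which is also in the interstitial matrix list, and PDGFRB (2.51 and 5.16 CPM). The fibroblast list lost its call without EGFP positive library 2 (0.067), without EGFP negative library 1 (0.14), with no filter on low counts (0.26), by limma-voom (0.076) and by fry (0.1). Only 7 of 16 endothelial markers and 9 of 16 luminal breast markers passed the count filter. The endothelial CDH5 and ERG had 0 counts in each library, and the luminal ESR1 had 0 to 2. Endothelial markers had 4 higher and 0 lower of 7 (4 and 1 adjusted over the list alone, camera adjusted p = 0.059), with PECAM1 at 0.78 and 3.41 CPM. They passed without EGFP positive library 1 (0.041) or EGFP negative library 2 (0.021). Luminal breast markers had 5 higher and 1 lower of 9 (5 and 1 adjusted over the list alone; adjusted p = 0.072; 0.005 without EGFP negative library 2), among them SPDEF (43.2 and 68.5 CPM).

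By chromosome, the genes of chromosome 12 were higher and those of chromosome 18 lower in EGFP negative cells as a whole, though on chromosome 12 the bin from 100 to 120 Mb was called lower (median -0.142 over 135 genes, adjusted p = 0.018). On chromosome 12 the median log2 fold change of 858 tested genes was 0.154, with 213 genes higher and 70 lower (camera adjusted p = 0.0033). On chromosome 18 the median of 244 genes was -0.179, with 8 higher and 49 lower (adjusted p = 0.0013). The other 21 chromosomes did not pass, including chromosome 4 at -0.098 (adjusted p = 0.069), which passed by limma-voom (0.037) and without EGFP positive library 1 (0.05, rounded) or EGFP negative library 2 (0.019). Both calls were lost with an estimated correlation (adjusted p = 0.37 for chromosome 12 and 0.88 for chromosome 18) and by fry (0.088 for each). In bins of 20 Mb, 24 of 162 passed, 10 higher and 14 lower. Bins were tested by camera with the preset correlation only, not by the tests under which both chromosome calls were lost. Of the bins that passed, those with medians above 0.2 were on chromosome 12 from 0 to 60 Mb (0.292, 0.23 and 0.32), chromosome 6 from 160 Mb (0.318), chromosome 21 from 40 Mb (0.27) and chromosome 1 up to 20 Mb (0.211). Those below -0.2 were on chromosome 4 from 40 to 80 Mb (-0.365 and -0.354), chromosome 18 from 40 to 80 Mb (-0.282 and -0.222), chromosome 2 from 80 to 100 Mb (-0.231), chromosome X from 100 to 140 Mb (-0.201 and -0.23) and chromosome 8 from 140 Mb (-0.213). COL6A1, COL6A2 and COL18A1 lie in the chromosome 21 bin. LAMA5 lies in the chromosome 20 bin from 60 Mb, which was called higher (median 0.081, camera adjusted p = 0.038). LAMA5 and these collagen genes were part of the bin tests, and no bin was tested without them. Their log2 fold changes, 1.14 to 3.44, were far above the medians of their bins. Other named genes, among them TNS2 and KRT81, lie in the first 60 Mb of chromosome 12. Counts relative to a library's total cannot show a change of all chromosomes together.

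**Figure D3:**
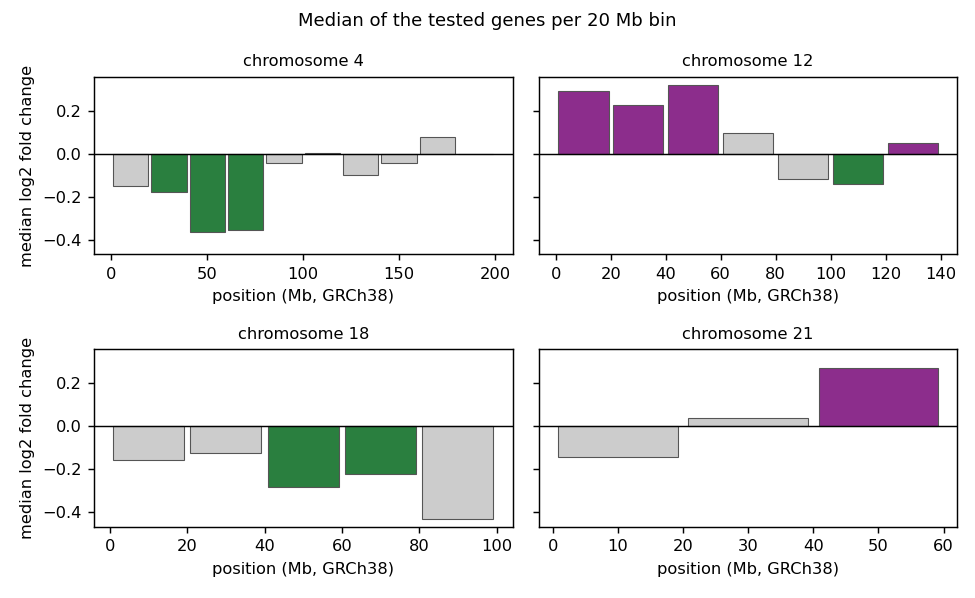
Median log2 fold change, EGFP negative over EGFP positive, of the tested genes in each 20 Mb bin of chromosomes 4, 12, 18 and 21, by position in Mb on GRCh38. Coloured bars passed adjusted p 0.05 over 162 bins by camera with a preset correlation, the only test of bins, and grey bars did not. The first 3 bins of chromosome 12 reach 0.292, 0.23 and 0.32.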

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

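The correction for GC content and length was chosen after the data were seen; 85.7% of tested genes had values for it. No called gene, list or chromosome among those named changed direction under any alternative run. Of the 150 named genes that passed, 150 passed with RLE factors, upper quartile scaling, limma-voom and that correction, 143 with DESeq2, 146 with no filter, and 120 to 150 with 1 library left out. Under TMM, RLE and upper quartile scaling the median of all genes was -0.003 to 0.012. Counts of called genes were 372 higher and 325 lower at 2-fold, and 1044 higher and 997 lower with DESeq2. All 2041 of the DESeq2 calls were also calls of the edgeR test. The GC and length correction raised the counts to 2088 higher and 2269 lower, and 3084 of those calls were also calls of the main test. With no filter on low counts they fell to 1199 higher and 1213 lower. The cause was not tested. With 1 library left out, 720 to 2477 genes were higher and 715 to 2465 lower. Leaving out EGFP positive libraries 1 and 2 gave the low values, and leaving out EGFP negative libraries the high ones; the lone library is assumed to vary like the other group, and the EGFP negative libraries differed more from each other. The labels do not say that equal numbers pair libraries; same-numbered libraries deviated with a correlation of 0.16. With the replicate block 2297 genes were higher and 2407 lower, and all 3095 calls were kept. Lists called numbered 0 by camera with an estimated correlation (5 at an unadjusted p under 0.05), 20 by limma-voom and 11 to 25 with 1 library left out (25 without EGFP negative library 2). Chromosomes called numbered 0 with an estimated correlation (1 unadjusted) and 0 by fry (3 unadjusted), and 12 had at least 1 called bin of 20 Mb. The cause of these moves was not tested either. Only results that passed in neither fit changed direction. The tested direction of 2 lists turned at means of -0.08 (cell-cell junctions, limma-voom) and -0.05 (immediate early genes, stricter filter). With 1 library left out, H2BC12 ranged from -0.21 to 0.24 and H2BC18 from -0.64 to 1.01, and list means from -0.06 to 0 (ATF4 and amino acid stress), -0.01 to 0.02 (cytokinesis and centrosome), -0.06 to 0.19 (cytosolic ribosomal proteins), -0.08 to 0.12 (epithelial state) and -0.29 to -0.06 (immediate early genes). Depth limits genes near 0.237 to 0.262 CPM.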

Other observations

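The tests on leukocyte RNA and on copies and a few strong genes of a chromosome 12 segment, and the gene lists in the next paragraph, were chosen after the results were seen, as was the GC and length correction; the other tests were set before their results.

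Targets of NRF2, the regulator of antioxidant and detoxifying enzymes, had 11 higher and 1 lower of 21 in EGFP negative cells (12 and 1 adjusted over the list alone). Beside ALDH3A1, these were AKR1C3 (3.08 and 26.1 CPM in EGFP positive and negative cells), NQO1 (131 and 331 CPM) and the transporter gene ABCC3 (5.24 and 22.8 CPM), while GCLM (70.5 and 73.7 CPM) and HMOX1 (14.4 and 13.4 CPM) did not pass. AKR1C genes are near-identical copies, so their levels are uncertain. Guidance genes also differed: SEMA3F rose from 15.4 to 65.1 CPM, SEMA6B from 41.2 to 142 CPM and PLXNA4 from 1.17 to 10.8 CPM, while SEMA3E fell, with 10 higher and 5 lower of 22 semaphorin and plexin genes (10 and 7 adjusted over the list alone). Of the hemidesmosome genes 4 were higher and 0 lower of 9 (5 and 2 adjusted over the list alone), ITGB4, LAMA3 (59.2 and 105 CPM), COL17A1 (9.66 and 22.8 CPM) and CD151, while LAMB3 was at 892 and 770 CPM and PLEC at 2740 and 3150 CPM. The keratin genes KRT81, KRT83, KRT86 and KRT19 rose and KRT18 (426 and 398 CPM) did not pass; 4 were higher and 0 lower of 10 keratins (5 and 0 adjusted over the list alone). Wnt genes had 3 and 3 of 12 (3 and 3 adjusted over the list alone), with DKK1 falling from 702 to 216 CPM, cancer-testis genes 3 and 1 of 5 (3 and 1 adjusted over the list alone) and clustered protocadherins 5 and 1 of 10 (6 and 1 adjusted over the list alone). Adjusted over these 7 lists, camera gave 2.5e-11 for NRF2 targets, 3.4e-04 for semaphorins and plexins, 4.8e-07 for hemidesmosome genes, 3.2e-09 for keratins, 0.04 for Wnt genes, 6.2e-09 for cancer-testis genes and 0.0059 for protocadherins. With an estimated correlation the adjusted p-values were 0.078 to 0.22, so none passed. Because these lists were picked from genes seen to change, their tests are not independent evidence. Near-identical copies, such as KRT81 and KRT83 or the AKR1C genes, were counted as separate members although their reads may be shared.

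Genes in the first 60 Mb of chromosome 12 were higher in EGFP negative cells, with a median log2 fold change of 0.296 over 458 genes (95% bootstrap interval over genes 0.261 to 0.326), 155 higher and 15 lower. A GC and length trend is argued against, since the median was 0.295 after the correction. That median is no test of whether a few strong genes made the rise, since bins with high medians were the ones chosen. The bootstrap interval does not allow for that choice. What the counts do describe is a rise called in 155 of the 458 genes, with 15 lower. More copies of the segment in the EGFP negative population cannot be told apart from regional regulation: the segment was chosen for its high bins, so the 78.8% of its genes above the median of all other genes restates that choice, and no DNA was measured here. The difference in extravasation that the labels name stays open too.

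LAPTM5 and CSF1R, genes best known from leukocytes, were higher in EGFP negative cells. RNA from leukocytes is argued against: PTPRC, TYROBP and FCER1G, abundant in leukocytes, together reached 0.256% of the LAPTM5 level in EGFP negative cells, and TYROBP and CD3E had 0 counts in each of the 4 libraries. With CD74, which tumour cells also express and which rose from 161 to 299 CPM, the sum was 206% of LAPTM5, nearly all of it CD74. Other genes known from leukocytes rose too: MYO1F from 3.51 to 35 CPM, CD96 from 0.52 to 18.9 CPM, ARHGAP30 from 0.823 to 9.89 CPM and CYTH4 from 1.26 to 8.75 CPM. That the cancer cells themselves transcribe LAPTM5 and CSF1R more may hold as a hypothesis; a difference tied to extravasation was not separately tested.

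Glycolysis genes were higher in EGFP negative cells, and 5 of the 20 lie on chromosome 12. Shifts of the regions around them do not account for the whole of it, since the median log2 fold change of 0.425 (95% bootstrap interval over genes 0.198 to 0.596) was 0.325 (0.136 to 0.418) once the median of each gene's 20 Mb bin was subtracted. A GC and length trend is argued against in the same way, with a median of 0.384 (0.204 to 0.571) after the correction. A coordinated regulation of glycolysis in the EGFP negative cells may remain as a hypothesis, and culture density or medium, of which the labels give nothing per group, stays open.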
